A study of Ovis aries with 36 samples.

How the data were processed

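The deposited table holds whole-number read counts per gene in 36 libraries, 1 for each of 4 brain regions of 9 lambs. Per the labels' protocols, flash-frozen tissue was used for RNA extraction, and libraries were made from enriched, fragmented mRNA with random priming. Per the series' design text and the submitters' processing notes, the authors trimmed paired reads with fastp, checked them with SeqKit, aligned them with STAR to the Ensembl release 107 sheep genome and deposited STAR's gene counts from its unstranded column. Versions of these tools and the name of the assembly are not given in the sources used here. Because strand was not used in the counting, reads of a gene and of an antisense or overlapping partner cannot be told apart, and reads shared by near-identical copies may be missing from both. In the table, 2828 genes were at 0 in every library.

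Columns were assigned to samples by their names, which are unique in the labels, and arm, region, sex and lamb were taken from the labels. The lambs are separate animals, so the spread between libraries of a group is between animals. No library was a copy of another: over 48 pairs of libraries of the same region and arm, the chi-square of their counts per degree of freedom was 8.574 to 219.5. Depth per library was 8782652 to 18153142 counts. The labels give no sequencing batch, and the split in depth between lambs A, H and I and lambs B to G was treated as a possible batch.

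Gene symbols could not be assigned. The reference table used here (35057 sheep genes, assembly ARS-UI_Ramb_v3.0) pairs none of the Ensembl identifiers with a symbol, so the match was 0%. The 32 gene lists fixed before the data were examined (brain cell types, myelin, hypoxia, inflammation and others) were therefore not tested, and checks on gene length, GC content and sex-linked genes were void. Before the data were examined, the genes to name were set as those with the largest positive and negative log2 fold changes per comparison among called genes with a symbol, a mean of at least 1 log2 CPM and no overlap between the arms. The requirement of a symbol was dropped, and at most 2 identifiers in each direction are given per comparison, leaving out those with at most 6 counts in every library of the lower group, a cut set after the values were seen. Others that met the rule were left out for brevity. Genes named because a count was very small were chosen after their values were seen.

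Counts were tested with edgeR 4.0.16 in R 4.3.3. Each region was fitted by itself over its 9 libraries with arm as the factor, TMM scaling factors, the filterByExpr filter, the quasi-likelihood F-test and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. All 3 arms shared the estimate of the spread because 2 of the arms hold 2 lambs each. Within a region the arms hold different lambs, so no pairing between arms exists. The same test was run on counts summed per lamb. Differences between regions in the change between arms, and differences between regions as such, were tested over all 36 libraries with the lamb as a block. The 4 regions come from the same animal, and deviations of libraries of the same lamb from their group means correlated at 0.12 to 0.23 on average over pairs of regions, with a lowest single value of -0.02. Levels are CPM with TMM factors, and log2 CPM was computed with a prior count of 2. The log2 values and fold changes were computed here from the deposited counts.

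For the axis from preterm to late preterm, the 500 genes with the largest difference between 1 preterm and 1 late preterm lamb gave the direction, the other lamb of each arm gave the points 0 and 1, and the mean over the 4 choices is reported. For the match to regions, each library was centred on the mean of the 4 region profiles of the other 8 lambs and correlated with each centred profile.

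The tests of arms within a region and of differences between regions in that change were tried on simulated counts. These had the real means and library sizes, with 200 genes changed. No such trial was made of the summed counts, the comparison of regions as such or the match to regions. In the motor cortex (16173 genes), 51% of 2-fold and 88% of 4-fold changes were recovered for supported against preterm lambs, 55% and 81% for supported against late preterm, and 48% and 77% for late preterm against preterm. In the cerebellum (16304 genes), the recovered shares of 4-fold changes were 48%, 39% and 7% in the same order. In the test of differences between regions (17265 genes), the 4-fold changes were placed only in the cerebellum of the supported lambs. No lamb effect was simulated. For supported against preterm lambs, 49.5% of these changes were recovered. For the axis a separate simulation started from the preterm means and changed a much larger random share of the genes. Simulated lambs placed at 1 on the axis were recovered at 0.97 to 1.02. Lambs placed at 0.5 were recovered at 0.5 to 0.51 in 3 regions but at 0.41 in the cerebellum.

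The alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no filter on low counts, sex as a covariate, a fit of only the arms compared, leaving out each lamb in turn, limma 3.58.1 for the summed counts, a fit without the block for the interaction, and other numbers of genes for the axis. Thinning all libraries to the lowest total, the depth group as a term, leaving out single regions or doubted libraries, the use of 1 preterm lamb as the reference of each comparison, and the comparison of regions as such with its alternatives were added after the data had been seen.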

Results

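Brain tissue from 9 lambs was profiled by RNA sequencing in 4 regions, the hippocampus, motor cortex, basal ganglia and cerebellum, which gave 36 libraries. The 5 lambs of the supported arm (A to E) were born preterm, cannulated at once and kept on EXTEND, a system that supports a preterm lamb outside the uterus, until they neared the age of the late preterm arm. The 2 late preterm lambs (F and G) were delivered at 127 days of gestation and examined at once, and the 2 preterm lambs (H and I) were examined at once after preterm delivery. The age of the preterm lambs and the exact age of the supported lambs are not given in the labels. Each arm therefore held different animals, and each animal gave 1 library per region. Both late preterm lambs were male, 4 of the 5 supported lambs were female, and the preterm arm held 1 lamb of each sex.

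Total counts per library ran from 8782652 to 18153142. The 12 libraries of lambs A, H and I held 8782652 to 13020225 counts and the 24 libraries of lambs B to G held 13765297 to 18153142, so that both preterm lambs and 1 supported lamb lay in the shallower group. Genes are given by their Ensembl identifiers, since none of the identifiers could be paired with a symbol here. Coordinates and the function of each gene are therefore not given, and known overlapping or antisense genes could not be marked.

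The first question was how far the 4 regions differed from each other. The cerebellum differed from each of the other 3 regions in 7949 to 8451 of 17450 tested genes (edgeR quasi-likelihood F-test with the lamb as a block, Benjamini-Hochberg adjustment, 9 libraries per region). The motor cortex differed from the basal ganglia in 998 genes, 421 higher in the motor cortex and 577 higher in the basal ganglia, and from the hippocampus in 69 genes. The hippocampus and the basal ganglia differed in 2 genes, with 1087 genes at an unadjusted p under 0.05 (702 without lamb D). Both were higher in the basal ganglia and are named because they were so few. ENSOARG00000015428 was at 109 ± 63.9 CPM (SD, n = 9) in the basal ganglia against 33.8 ± 21.4 CPM in the hippocampus (edgeR log2 fold change 1.66, adjusted p = 0.0253), and ENSOARG00000012587 was at 6.49 ± 8.71 against 0.22 ± 0.425 CPM (log2 fold change 4.41, adjusted p = 0.0251). Leaving out the cerebellum libraries of lambs D, G and H, which stood apart as described next, raised the motor cortex to basal ganglia count to 2726 and the hippocampus to motor cortex count to 143. With 1 lamb left out at a time, hippocampus against motor cortex gave 16 (without lamb E) to 175 (without lamb H) genes, motor cortex against basal ganglia 349 (without E) to 1972 (without H), and hippocampus against basal ganglia 0 when A, D, E, G or H was left out. Without the lamb block the counts that moved by over 1.5 times were 125 for hippocampus against motor cortex and 9 for hippocampus against basal ganglia.

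Each library was then correlated, across genes, with the mean profile of each region in the other 8 lambs. All 9 motor cortex and all 9 cerebellum libraries matched their own region best. Of the 9 hippocampus libraries, 5 matched another region better, namely lambs B and E the basal ganglia and lambs G, H and I the motor cortex. Of the 9 basal ganglia libraries, 5 also matched another region better, namely lambs A, C, F and G the hippocampus and lamb I the motor cortex. These 10 libraries included both preterm hippocampus libraries and both late preterm basal ganglia libraries. Among the cerebellum libraries, the correlation with the own region was 0.49 in lamb D, 0.59 in lamb G and 0.21 in lamb H, and 0.75 to 0.85 in the other 6.

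**Figure D1:**
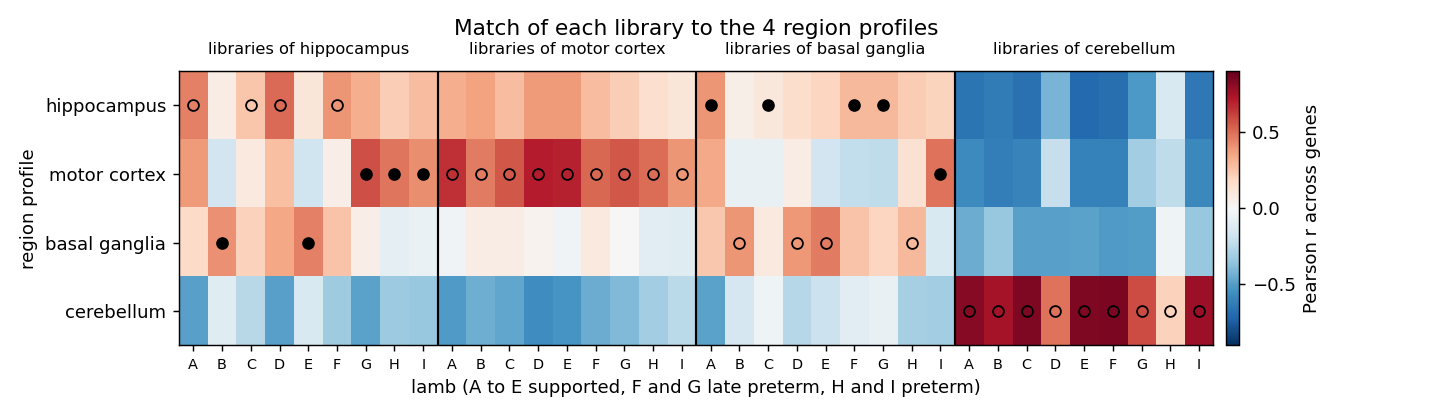
Pearson correlation across genes (colour) of each of the 36 libraries (columns, by labelled region and lamb) with the mean profile of each region in the other 8 lambs (rows). A circle marks the best match of a library, open where it is the labelled region and filled for the 10 libraries of hippocampus and basal ganglia where it is another region.

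The comparison of supported with preterm lambs asked what had changed in the brain by the end of support. In the motor cortex, 1980 of 16173 tested genes differed, 1044 higher and 936 lower in the supported lambs (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05, n = 5 and 2). Their median absolute log2 fold change was 0.74, and 573 of them changed at least 2-fold. ENSOARG00000009539 rose from 1.11 ± 0.771 CPM (SD, n = 2) in the preterm lambs to 19.8 ± 6.46 CPM (n = 5) in the supported lambs, a log2 fold change of 4.11 ± 0.52 (SE, edgeR adjusted p = 0.00131). ENSOARG00000014486 rose from 0.415 ± 0.352 to 7.12 ± 3.3 CPM (log2 fold change 4.12 ± 0.80, edgeR adjusted p = 0.00937). ENSOARG00000004367 was lower, at 0.617 ± 0.589 CPM against 16.2 ± 19.7 CPM (log2 fold change -4.69 ± 0.84, edgeR adjusted p = 0.00626), and so was ENSOARG00000003454, at 0.783 ± 0.332 against 8.16 ± 8.05 CPM (log2 fold change -3.35 ± 0.59, edgeR adjusted p = 0.00574). For these last IDs the preterm mean rests on 2 lambs that differ widely, at 2.28 and 30.2 CPM for the former and 2.47 and 13.9 CPM for the latter. Without lamb H both calls were lost, at log2 fold changes of -1.86 (edgeR adjusted p = 0.296) and -1.63 (edgeR adjusted p = 0.169), and so was that of ENSOARG00000014486 (3.41, edgeR adjusted p = 0.0728). No comparison of supported with preterm lambs within a depth group has replicates in both arms. The shallower group holds both preterm lambs and only lamb A of the supported arm. With the depth group as a term, 171 genes were called, 140 higher and 31 lower. Of the IDs named here, only ENSOARG00000009539 kept its call with this term. Over the 1980 genes, the median log2 fold change in the direction first called was then 0.72 with a median SE of 0.22, against 0.74 with a median SE of 0.15 before. Lamb A carries the contrast with this term and was also among the lambs used to choose these genes. The kept size is therefore not independent evidence against a batch. Without preterm lamb I the count was 607, and without preterm lamb H it was 1182.

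In the hippocampus, 413 of 16370 tested genes differed between supported and preterm lambs, 216 higher and 197 lower in the supported arm, with a median absolute log2 fold change of 1.02. ENSOARG00000002491 was at 903 ± 672 CPM (SD, n = 5) in the supported lambs and at 6.44 ± 3.93 CPM (n = 2) in the preterm lambs (log2 fold change 7.12 ± 1.23, edgeR adjusted p = 0.0383). With the depth group as a term its log2 fold change was 4.37 (edgeR adjusted p = 0.445). ENSOARG00000010518 was at 1.9 ± 0.872 CPM in the supported and 25.8 ± 11.2 CPM in the preterm lambs (log2 fold change -3.76 ± 0.44, edgeR adjusted p = 0.0201). In the motor cortex ENSOARG00000002491 had a much smaller change of the same sign and was not called (edgeR adjusted p = 0.48). ENSOARG00000010518 was called there (log2 fold change -2.67, edgeR adjusted p = 0.00113). Of the genes called in the hippocampus and measured in the motor cortex, 211 of 216 higher and 196 of 197 lower genes had the same sign there, and 117 and 129 were called in both regions, where independent lists would share 14.1 and 11.5. In the cerebellum 123 of 215 higher genes (57.2%) and 96 of 197 lower genes (48.7%) had the same sign, but this rested on the library of lamb H, which is described below. Without it 177 of 216 (81.9%) and 147 of 197 (74.6%) had the same sign. The hippocampus and motor cortex samples come from the same lambs, so the lists are not independent. Both preterm hippocampus libraries matched the motor cortex profile better than their own, as given above. The count was 0 without preterm lamb H or I and with the depth group as a term, between 40 and 86 without any of lambs B, C, E, F or G, where lower genes were in excess except without B, 939 without lamb A, 79 when only the supported and preterm libraries were fitted, and 2138 in DESeq2. With the depth term the median log2 fold change in the direction called went from 1.02 to 0.89 and its median SE from 0.17 to 0.25. Here too lamb A, which carries that contrast, was among the lambs used to choose the genes.

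In the basal ganglia, no gene of 16679 passed the threshold between supported and preterm lambs in edgeR, while 2028 genes (12.2%) had an unadjusted p under 0.05 and DESeq2 called 567. The unadjusted count was 734 without lamb I, whose basal ganglia library matched the motor cortex, 920 with only the libraries that matched their own region best, and 1135 with the depth group as a term. The genes that passed in the motor cortex leaned the same way here, 906 of 1040 of the higher and 849 of 933 of the lower ones, though in the same lambs. The smallest adjusted p was 0.0604. On simulated counts at this size, 12% of 2-fold and 61% of 4-fold changes were recovered for this comparison, over 16679 genes.

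In the cerebellum, 1561 of 16304 tested genes differed between supported and preterm lambs, 432 higher and 1129 lower in the supported arm, with a median absolute log2 fold change of 1.63. Of the 2 preterm libraries, that of lamb H stood apart, lying at least 4-fold away from the mean of the other 8 cerebellum libraries in 3901 of 17450 genes, against 72 to 291 genes for each of those. ENSOARG00000024494, for example, was at 119 ± 7.65 CPM (SD, n = 5) in the supported lambs and at 240 and 6410 CPM in the 2 preterm lambs (log2 fold change -4.80 ± 0.78, edgeR adjusted p = 0.0243), a log2 fold change that was -1.02 without lamb H. With lamb H left out, so that lamb I alone stood for the preterm arm and was assumed to vary like the other groups, 660 genes differed, 337 higher and 323 lower. Of these, 294 of 335 higher and 305 of 319 lower genes measured in the motor cortex had the same sign there, and 164 and 169 were called in the motor cortex, where independent lists would share 21.8 and 18.7. These lists are not independent either, since both regions come from the same lambs and lamb I, the only preterm cerebellum left, is also 1 of the 2 preterm lambs of the motor cortex. With the libraries of lambs D, G and H all left out, 1259 genes were called, 800 higher and 459 lower. The count was 0 without any of lambs A, B, C or E and with the depth group as a term, 57, 58 and 70 without lambs D, F and G, 74 when only supported and preterm libraries were fitted, 3209 with sex as a covariate, 10263 without lamb I (5455 higher, 4808 lower) and 4144 in DESeq2. With the depth term the median log2 fold change in the direction called was 1.61 against 1.63, and its median SE was 0.59 against 0.36. As in the motor cortex, lamb A carries that contrast and helped to choose the genes, so the kept size is not independent evidence.

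The comparison of supported with late preterm lambs set lambs side by side whose ages the series' design text describes as similar. No gene passed the threshold in the hippocampus, motor cortex or cerebellum in edgeR. At an unadjusted p under 0.05 there were 796 genes (4.86%) in the hippocampus, 2661 (16.5%) in the motor cortex and 194 (1.19%) in the cerebellum, and DESeq2 called 25, 611 and 7 genes. The unadjusted counts moved with sex as a covariate, to 1213 in the hippocampus and 1100 in the motor cortex, and without lamb G, to 370, 1361 and 88 in the 3 regions. The hippocampus count was 1212 without lamb D. The cerebellum count was 129 without lamb E, 427 without D, 732 without H, 735 without I, 532 without the libraries of D, G and H, and 703 when only the compared arms were fitted. The smallest adjusted p was 0.864 in the hippocampus, 0.0686 in the motor cortex and 1 in the cerebellum. For the motor cortex, 89 genes were called without late preterm lamb F, 2 without lamb C, 6 without lamb H and 43 without the filter on low counts. The absence of calls does not show that the arms were alike. On simulated counts, 55% of 2-fold changes were recovered in the motor cortex (16173 genes), 18% in the hippocampus (16370 genes) and 1% in the cerebellum (16304 genes).

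In the basal ganglia, 48 genes differed between supported and late preterm lambs, 14 higher and 34 lower in the supported arm, and 47 of them by at least 2-fold. ENSOARG00000004940 was at 75.7 ± 37 CPM (SD, n = 5) in the supported and 0.905 ± 1.01 CPM (n = 2) in the late preterm lambs (log2 fold change 6.42 ± 0.85, edgeR adjusted p = 0.0331). ENSOARG00000012352 was at 23.6 ± 15.2 CPM in the supported and 502 ± 71.9 CPM in the late preterm lambs (log2 fold change -4.41 ± 0.52, edgeR adjusted p = 0.028). Both late preterm basal ganglia libraries matched the hippocampus profile better than that of the basal ganglia. The count was 0 without lamb F or G and with sex as a covariate, 4 without lamb H or I and when only the compared arms were fitted, 14 without lamb A and with the depth group as a term, and 11 and 17 without lambs B and D. Without lamb C it was 233 (129 higher, 104 lower) and in DESeq2 1028 (678 higher, 350 lower), so the excess of lower genes turned in both. With sex as a covariate the log2 fold changes of the IDs named here were 6.11 and -5.31.

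The comparison of late preterm with preterm lambs described the difference between the 2 arms of unsupported lambs. In the motor cortex 418 genes differed, 252 higher and 166 lower in the late preterm lambs, with a median absolute log2 fold change of 0.93 (edgeR, n = 2 and 2). ENSOARG00000009539, which also rose in the supported lambs, was at 15.8 ± 5.6 CPM against 1.11 ± 0.771 CPM (log2 fold change 3.78 ± 0.55, edgeR adjusted p = 0.0119). ENSOARG00000017688 was at 21.8 ± 12.8 CPM in the late preterm and 120 ± 51.6 CPM in the preterm lambs (log2 fold change -2.46 ± 0.45, edgeR adjusted p = 0.0254). In the basal ganglia, ENSOARG00000020816 was higher (24.2 ± 1 against 4.23 ± 0.467 CPM, log2 fold change 2.51 ± 0.22) and ENSOARG00000008181 lower (69.3 ± 4.24 against 366 ± 18.6 CPM, log2 fold change -2.40 ± 0.20), each with an edgeR adjusted p of 0.014. These were the 2 genes called there, where 2717 genes had an unadjusted p under 0.05. No gene passed in the hippocampus (1387 at an unadjusted p under 0.05, 175 in DESeq2) or the cerebellum (3648 and 1399), and the cerebellum count was 9512 without lamb I, 1 without lamb H and 241 without the libraries of lambs D, G and H. The unadjusted counts were 1231 in the basal ganglia, 785 in the hippocampus and 10407 in the cerebellum without lamb I, 1300 and 1377 in the basal ganglia and the cerebellum without lamb G, 1551, 587 and 1575 in the basal ganglia, hippocampus and cerebellum without lamb F, and 824 and 2107 in the hippocampus and cerebellum without lamb H. The unadjusted hippocampus count was 2372 when only these libraries were fitted and 449 with the depth group as a term. Depth and arm coincide here, and with the depth group as a term no gene was called in any region. The log2 fold changes were then 3.56 for ENSOARG00000009539 and -2.28 for ENSOARG00000017688 in the motor cortex, so the loss of calls does not show that depth made the difference. The motor cortex count was 12 without lamb G, 20 without H, 279 without I (100 higher and 179 lower, so that the balance turned), 193 without E, 215 without A, 270 without D and 765 without F, 200 with sex as a covariate, 24 when only these libraries were fitted and 1305 in DESeq2. The basal ganglia count was 0 without any of lambs E to I and with sex as a covariate, 4 and 12 without lambs B and C, 28 without the filter, 865 when only these libraries were fitted and 900 in DESeq2.

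**Figure D2:**
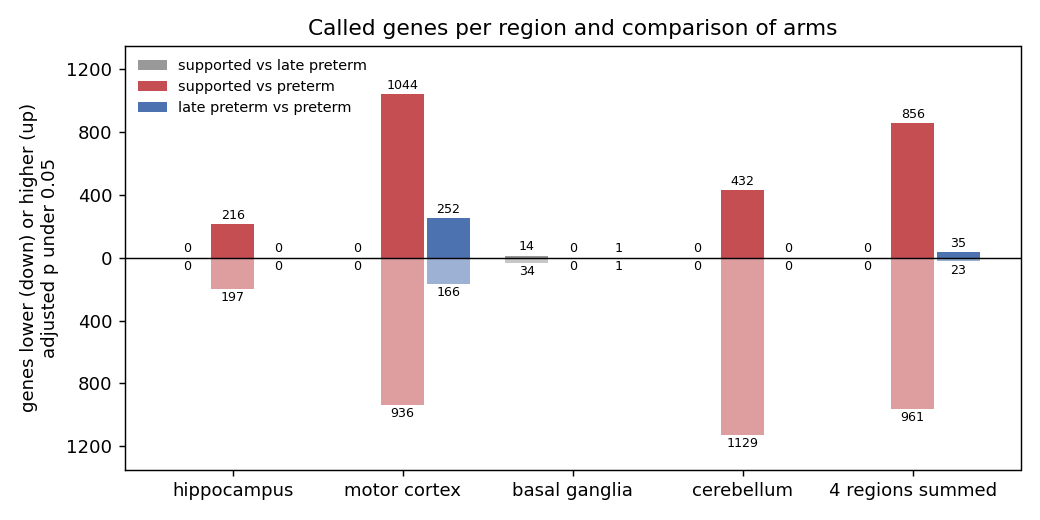
Number of genes past an adjusted p of 0.05 (edgeR) that were higher (dark bars, up) or lower (pale bars, down) in the first-named arm, for each region and for counts summed per lamb, with 5 supported, 2 late preterm and 2 preterm lambs. The motor cortex held 1980 genes for supported against preterm, 418 for late preterm against preterm and 0 for supported against late preterm lambs.

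The supported and the late preterm lambs were then compared through their shared reference, the preterm lambs. Within the motor cortex, 222 genes were higher and 144 lower in both, out of the 252 and 166 called for the late preterm lambs. Independent lists would share 16.3 and 9.61, but these lists share their preterm libraries. The fold changes of the 2 comparisons correlated across genes at r = 0.71, with a covariance of 0.207. In 20 simulations of unchanged arms, where both comparisons shared simulated preterm libraries, r was 0.61 and the covariance 0.0785. The covariances differed by 0.128. Over all genes of the motor cortex, 74.9% had the same sign in both comparisons, against 70.8% in the simulations. The hippocampus gave r = 0.79 against 0.61 simulated (covariance 0.318 against 0.145) and the cerebellum r = 0.93 against 0.62 (covariance 0.896 against 0.195). The basal ganglia gave r = 0.49, below the 0.6 simulated, with 71.3% of genes of the same sign against 70.7%, although the covariance was 0.271 against 0.17. Both cerebellum comparisons hold lamb H, whose library stood apart and shifts both fold changes the same way, while the simulations assumed a preterm spread like that of the other groups. With lamb H as the reference of 1 comparison and lamb I of the other, so that no library was shared, r was 0.4 and 0.19 in the motor cortex over the 2 ways to assign them, where simulations gave 0. It was 0.44 and 0.51 in the hippocampus, 0.2 and 0.24 in the basal ganglia and 0.28 and 0.27 in the cerebellum, with 0 in the simulations. This split was made after the data were seen, genes are not independent replicates, and both preterm lambs lie in the shallower group, so a batch would be shared as well. Both preterm hippocampus libraries matched the motor cortex best, so a difference in the pieces could be shared there too. The simulations held neither.

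Each supported lamb was also placed on an axis from preterm (0) to late preterm (1), drawn with 500 genes chosen in 1 lamb of each of those arms and scaled with the others. In every region the preterm end rests on lambs of the shallower group and the late preterm end on male lambs of the deeper group. A position may therefore reflect depth group or sex as well as age. For the motor cortex the supported lambs lay at 0.89 ± 0.24 (SD, n = 5), from 0.62 to 1.23. The mean moved from 0.63 to 1.24 over the 4 choices of lambs. In the basal ganglia the supported lambs lay at 0.22 ± 0.19 (SD, n = 5), with a mean of 0.17 to 0.28 over the 4 choices. The ends of that axis rest on libraries that matched other regions, both late preterm lambs the hippocampus and preterm lamb I the motor cortex, so the value may reflect the pieces as well as age. The hippocampus gave 2.08 ± 0.93 with a mean of 1.09 to 3.73 over the choices, on an axis whose preterm libraries, and that of late preterm lamb G, matched the motor cortex. The cerebellum gave 3.19 ± 4.22, where lamb D lay at 10.67 and the mean without it was 1.32. There the axis was ill defined, since the held-out lambs of the 2 reference arms lay as little as 0.04 apart.

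**Figure D3:**
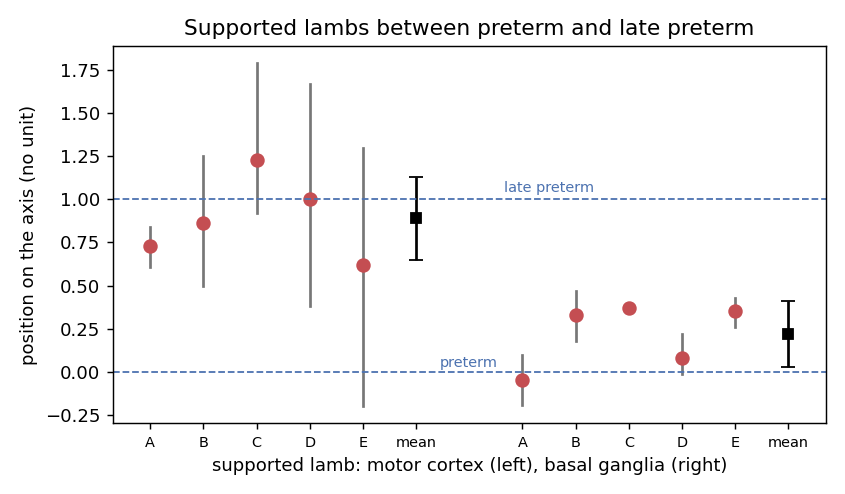
Position of each supported lamb (A to E, red points) between the preterm (0) and late preterm (1) lambs in the motor cortex and the basal ganglia, with grey lines for the range over the 4 choices of reference lambs and black squares for the mean and SD (n = 5). The motor cortex lambs lay from 0.62 to 1.23 and the basal ganglia lambs from -0.05 to 0.37.

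Summing the counts of the 4 regions per lamb gave 1817 genes of 18515 for supported against preterm lambs (856 higher, 961 lower), 58 for late preterm against preterm lambs (35 higher, 23 lower) and 0 for supported against late preterm lambs in edgeR, where 1121 genes had an unadjusted p under 0.05 (504 without lamb G, 679 with sex as a covariate) and DESeq2 called 105. ENSOARG00000018479 was lower, at 0.77 ± 0.19 CPM (SD, n = 5) in the supported and 9.25 ± 4.33 CPM (n = 2) in the preterm lambs (log2 fold change -3.59 ± 0.31, edgeR adjusted p = 0.00258). ENSOARG00000017453 was higher, at 12.1 ± 6.87 against 0.434 ± 0.261 CPM (log2 fold change 4.80 ± 0.85, edgeR adjusted p = 0.0109). With limma on the mean of the regions, the supported against preterm balance turned to 998 higher and 737 lower. Without the cerebellum the late preterm against preterm balance turned to 26 higher and 31 lower. The supported against preterm count was 284 without lamb H, 1166 without lamb I and 3254 in DESeq2. The late preterm count was 0 with sex as a covariate and without any of lambs B to H, 1 without lamb A, 233 without lamb I (58 higher and 175 lower, so that the balance turned) and 1175 in DESeq2 (582 higher, 593 lower).

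Whether a change differed between regions was tested with the lamb as a block in all 36 libraries. It differed in 3033 of 17450 genes for supported against preterm lambs, in 1 gene for late preterm against preterm lambs and in 0 for supported against late preterm lambs (edgeR quasi-likelihood F-test, 1548 genes at an unadjusted p under 0.05 in the last, from 366 without lamb G to 3127 without lamb H). The counts rested on the cerebellum, since without it the first and the second fell to 0. Without the lamb block the second was 619. Without lamb H the first count was 13 and without lamb I 8630, with values from 583 to 1867 when any other lamb was left out.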

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

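Of the tests in this part, those on an outside tissue, another region, swapped tubes, a shared batch, thinned motor cortex libraries, support against age and the make-up of the hippocampus pieces were chosen after the results were seen.

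In 20 groups of 5 supported lambs, 2 values lay apart from the rest, where chance gives about 1. The cerebellum library of lamb D had a correlation with its own region of 0.49, with the next at 0.75, and lamb D lay at 10.67 on the cerebellum axis, with the next at 2.17. The change from preterm to supported lambs differed between regions in 3033 genes and the change from preterm to late preterm in 1, ENSOARG00000017510, whose log2 fold change was 2.32 in the cerebellum and -0.41, -0.29 and -1.02 in the hippocampus, motor cortex and basal ganglia (edgeR adjusted p = 0.0075, chosen after its value was seen). Without lamb H the first count was 13 and without lamb I 8630, and the second was 0 without lamb C, G or H and 7946 without lamb I.

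The cerebellum library of lamb H stood at least 4-fold away from the other 8 in 3901 genes, 1484 higher and 2417 lower. Its lower depth is argued against, since the other libraries thinned to its total had at most 248 such genes, and so is another of the 4 regions, since its best match was the cerebellum at 0.21 with the next at -0.04. RNA from a tissue outside the 4 regions cannot be told apart from damage to the RNA: 30 genes found mainly in the cerebellum kept a median of 0.31 of their level, with quartiles of 0.146 and 0.686, where the 4-fold drops would need 0.25 or less, and the medians of the other 8 libraries, lambs D and G among them, were 0.574 to 1.17. Of its higher genes, 47 (3.17%) were under 1 CPM in every other library. RNA quality and a biological difference of this lamb were not tested.

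Several pieces did not match the region on their label alone. For lambs D and G a candidate explanation is a cerebellum piece that also held cortex, since separate sets of genes gave shares of 0.639 cerebellum and 0.395 cortex (sum 1.03) in lamb D and 0.638 and 0.32 (sum 0.958) in lamb G, against cortex shares of 0.02 to 0.037 in the unmixed libraries, whose cerebellum shares reached as low as 0.682 and so hardly separate them. A swap with the motor cortex tube is argued against, since the motor cortex libraries of these lambs matched the motor cortex over the cerebellum by at least 0.96 in correlation. For a swap of hippocampus and basal ganglia tubes, 0 of the 9 lambs had both out of place in the opposite sense. This cannot decide the question, since these regions differed in 2 genes and their profiles hold the same doubted libraries. How the pieces were cut, and whether these regions are hard to separate at this age, stays open and untested.

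The difference between supported and preterm lambs in the motor cortex is the third pattern. Depth as the whole cause is argued against, since 1980 genes were called after all libraries were thinned to the lowest total, and sex is as well, with 1854 genes called with sex in the model. A batch shared by lambs A, H and I cannot be told apart from the arm with only 1 supported lamb in it. Lamb A lay at 0.73 on the axis (0.61 to 0.84 over the choices of reference lambs) where the preterm lambs define 0. In the other regions lamb A lay lowest of the supported lambs, at 0.65 in the hippocampus, -0.05 in the basal ganglia and 0.52 in the cerebellum. A shared batch could place it there, but those axes are in doubt. Over genes called against 1 preterm lamb, the unsupported late preterm lambs F and G lay 0.38 to 0.82 of the way of the supported lambs from the other preterm lamb. With calls against lamb I, the lower quartile of the late preterm log2 change was -0.02 and 73.6% of genes had the same sign. Without a batch this would argue against support as the whole cause. Lambs F and G lie in the deeper group with most supported lambs, so a batch could place them there too and the question stays open. Support as a part of the cause cannot be told apart from age, with a mean position of 0.89 (0.63 to 1.24 over the choices). For the hippocampus, cortex in the preterm pieces was weighed as the whole cause. Of the genes called higher 97.7%, and of those called lower 99.5%, had the same sign in the motor cortex, where every library matched its own region best. That argues against it only if the motor cortex pieces were alike in make-up, which was not tested. Genes enriched in the motor cortex, described below, had medians of 0.73 and 0.13 log2 CPM there in preterm lambs H and I. The motor cortex libraries of the other lambs held 1.06 to 1.92. Both regions come from the same lambs. Whether the calls follow the difference between cortex and hippocampus was not tested, so a part played by the pieces stays open.

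Regrouping tested chance. For the motor cortex, the 7 supported and preterm libraries were split into 5 and 2. The real split gave 2097 genes and the highest of the other 20 gave 6, so 1 of 21 splits gave as many. This is the least share that 21 splits can give, and it is under 0.05 only without adjustment over the regions tested. Both preterm lambs also lie in the shallower depth group, so the split does not tell arm from batch. For the cerebellum the real split gave 74 and the highest other 3, again 1 of 21. Lamb H, whose library stood apart, widens the spread of the group it falls in. Splits that place it among the 5 may thus call few genes whatever the arm, so the rank says little about chance here. For the hippocampus the real split gave 79 and the split that set lambs B and E apart gave 651, so 2 of 21 gave as many and chance cannot be excluded. These 2 libraries were the hippocampus libraries that matched the basal ganglia, so the higher count points to a structure of the samples. For supported against late preterm basal ganglia the real split gave 4 and the split that set lambs B and D apart gave 181, so that 2 of 21 gave as many and chance cannot be excluded. Many more genes than in the real split point to a structure of the samples there too.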

How the results depend on the processing

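All alternatives on thinning, the depth group, left-out regions or libraries other than single lambs, a reference split between the preterm lambs, and the comparison of regions were chosen after the data were seen. With RLE size factors every count of changed genes stayed within 1.5 times, positions on the axis moved by less than the SD between lambs with other numbers of genes, RLE or 1 supported lamb left out, but by more with other reference lambs (0.63 to 1.24 in the motor cortex, 1.09 to 3.73 in the hippocampus, 1.06 to 8.13 in the cerebellum), and the largest shift of a correlation of fold changes with the same libraries was from 0.79 to 0.82. With 1 preterm lamb as the reference of each comparison, the correlations fell to 0.48 in the hippocampus, 0.3 in the motor cortex, 0.22 in the basal ganglia and 0.27 in the cerebellum. Among the pairs of a gene and a comparison that met the rule for naming, the 30 with the largest changes, at most 2 per direction and comparison, were followed. The report gives 15 of them. They kept their direction in all 454 alternatives and lost their call in 204, of which 144 left out a lamb. The kept direction says little, since the pairs were chosen in the same libraries for large changes without overlap between the arms. ENSOARG00000009539 (supported against preterm, motor cortex) and ENSOARG00000018479 (summed counts) kept their calls in all 15 of theirs. Where not stated, the cause of a shift was not tested. The gene lists could not be run without symbols.

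Calls below are in the order supported against late preterm, supported against preterm, late preterm against preterm. DESeq2 gave 25, 2138 and 175 in the hippocampus, 611, 2694 (within 1.5 times of 1980) and 1305 in the motor cortex, 1028, 567 and 900 in the basal ganglia, 7, 4144 and 1399 in the cerebellum and 105, 3254 and 1175 for summed counts. The depth group as a term, which leaves lamb A to carry the contrasts with the preterm arm, gave 0, 171 and 0 in the motor cortex, 0 in all of hippocampus and cerebellum, and 14, 0 and 0 in the basal ganglia. Sex as a covariate gave 0 for both basal ganglia counts of 48 and 2, 3209 for the cerebellum (1561), 200 for late preterm against preterm motor cortex (418) and 0 for the summed counts (58). The basal ganglia log2 fold changes stayed about as large with sex (ENSOARG00000020816 2.51 to 2.54, ENSOARG00000008181 -2.40 to -2.31), so the lost calls do not show an effect of sex. Fitting only the arms compared, with fewer libraries for the spread, gave 79 in the hippocampus and 74 in the cerebellum for supported against preterm, 24 in the motor cortex and 865 in the basal ganglia for late preterm against preterm, and 4 in the basal ganglia for supported against late preterm. Without the cerebellum the summed late preterm against preterm count was 57, and its balance turned to 26 higher and 31 lower. No filter gave 43 for supported against late preterm motor cortex and 28 for late preterm against preterm basal ganglia. Without the libraries of lambs D, G and H the late preterm against preterm cerebellum count was 241. For summed counts, limma on the mean of the regions gave 37 for late preterm against preterm and turned supported against preterm from 856 higher and 961 lower to 998 and 737, and limma voom with the lamb as a random effect gave 85, 2957 and 728.

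Without the replicate block the counts of genes whose change differs between regions were 0, 2707 and 619, and without the cerebellum 0, 0 and 0. Between regions, no replicate block gave 125 for hippocampus against motor cortex and 9 for hippocampus against basal ganglia and changed no other count by over 1.5 times. Leaving out the cerebellum libraries of lambs D, G and H gave 143 and 10 there and 2726 for motor cortex against basal ganglia. Within a region no paired analysis was possible because the arms hold different lambs.

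Leaving out 1 lamb at a time gave these ranges in the same order of comparisons. Where it left a single preterm or late preterm lamb, that lamb was assumed to vary like the other groups. Hippocampus counts ran 0 to 0, 0 to 939 and 0 to 0, motor cortex 0 to 89, 607 to 2060 and 12 to 765, basal ganglia 0 to 233, 0 to 0 and 0 to 12, cerebellum 0 to 0, 0 to 10263 and 0 to 9512, and summed counts 0 to 1, 284 to 1606 and 0 to 233. Changes that differed between regions ran 0 to 4, 13 to 8630 and 0 to 7946. Between regions the ranges were 16 to 175 (hippocampus and motor cortex), 0 to 3 (hippocampus and basal ganglia), 349 to 1972 (motor cortex and basal ganglia), and 7067 to 10378, 7486 to 10336 and 6860 to 10189 (cerebellum against hippocampus, motor cortex and basal ganglia). Thinning to the lowest total moved no count by over 1.5 times.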

Other observations

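Genes enriched in 1 region were followed in the comparisons of arms. These sets were drawn from the same libraries after the data were seen, so their direction is not independent evidence. They were the 894 genes at least 2-fold higher in the cerebellum, and 17 genes at least 2-fold higher in the motor cortex, than in each other region (edgeR with the lamb as a block).

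Over the regions, 5 such tests were made per comparison. In the motor cortex, 706 of the cerebellum genes were measured. Of these, 132 were lower and 24 higher in the supported than in the preterm lambs, with a median log2 fold change of -0.27 over the set (limma camera adjusted p = 1.96e-05 with a preset correlation, adjusted p = 0.342 with an estimated correlation). Late preterm against preterm lambs gave 13 lower and 6 higher, with a median of -0.17 (camera adjusted p = 0.0148, and adjusted p = 0.864 with an estimated correlation). Of the 17 motor cortex genes, 4 were higher and 1 lower in the supported than in the preterm motor cortex, with a median log2 fold change of 1.25 (camera adjusted p = 0.00216, and adjusted p = 0.342 with an estimated correlation), and in late preterm against preterm lambs 1 was higher, with a median of 1.46 (camera adjusted p = 0.00434, and adjusted p = 0.635 with an estimated correlation). The cerebellum set also passed with the preset correlation in supported against late preterm lambs, with medians of -0.10 in the hippocampus and -0.17 in the motor cortex (camera adjusted p = 0.00492 in each, and adjusted p = 0.531 and 0.733 with an estimated correlation), and no single gene of it was called there. No set therefore passed once the correlation between its genes was estimated.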
